A study of Mus musculus with 36 samples.

How the data were processed

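TBP binding was measured by CUT&RUN in RT7 and RT10 mouse ES cells, per the labels, with protein A-MNase cleavage and a yeast spike-in DNA whose use in the analysis is not given in the sources used here. Reads were trimmed with cutadapt 4.0, aligned with Bowtie2 2.4.4 to mm10 and called with MACS2 2.2.7.1, with SAMtools 1.15.1, bedtools and deepTools also named, per the submitters' processing notes, which give no roles or parameters; the role of each tool is taken from its usual use. The deposited values are −log10 q-values at each peak summit of TBP over IgG, as the peak names and the values of the lists show; the lowest was 1.30, close to the −log10 of a q of 0.05, and the threshold the authors set is not stated. Each line and treatment has 2 TBP libraries per the labels, and its list carries no replicate number. Whether the authors pooled the libraries is not stated. For the RT7 EtOH and RT10 4-OHT IgG libraries the treatment label differs from the title, and the title was used, as in the peak names.

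The score was used to rank, split and filter summits within a list, and scores of different lists were otherwise not compared. The exceptions were a score minimum of 10 set alike for all 4 lists, and genes missing from both 4-OHT lists, which were ordered by the mean of their 2 EtOH scores. As read depth is unknown, that minimum may not mean the same in each list. All 4 lists named 1 summit per peak and held no unplaced sequences. Summits were matched by distance, and a summit was called kept when the other list had a summit within 250 bp. Positions moved by 10 kb served as the chance level. Shares have exact Clopper-Pearson 95% intervals for counting error; read depth per library is unknown, so no precision from depth can be given. As there is 1 list per group, no test of the treatments was run and no p-value is given.

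Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the same assembly as mm10, with 49980 genes with coordinates. The table gives no strand, so the planned distance to a transcription start was replaced by the distance to the nearer end of a gene, within 500 bp. No genome sequence was used here, so the planned split by TATA box was not run. Summits were classed by the nearest gene end as protein-coding, RNA polymerase III (tRNA, U6, 5S, 7SK, 7SL, Rmrp, Rpph1, vault and Y RNA genes; 489 in the table), other, or none, with mitochondrial summits apart. Class and list shares were placed among 10000 random sets of EtOH summits drawn from 20 score bins, as a description of these lists. The summits drawn from included those of the class or list itself, which moves the expected share toward the observed one. For fixed lists of protein-coding genes the sets came from summits at protein-coding gene ends, and for RNA polymerase III and small nuclear RNA genes from summits at any gene end. Protein-coding gene ends were also compared with summits away from gene ends, weighted to the same scores, with 95% intervals from 10000 binomial draws within score bins. Sites without a 4-OHT summit in both lines were set against 10000 permutations of the RT10 labels within 20 bins of the mean EtOH score rank.

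The fixed lists covered pluripotency, lineage, two-cell-like, fibroblast, ribosomal protein, TFIID, SAGA and ATAC, RNA polymerase II and general factor, p53 target, immediate early and heat shock, glycolysis and cytoskeleton, small nucleolar RNA host, cholesterol synthesis, histone, RNA polymerase III and small nuclear RNA genes. A member was bound when a summit lay within 500 bp of either end. Named genes followed a rule set before the data were examined. Per line it took the 10 protein-coding genes with the highest EtOH score and no 4-OHT summit within 1000 bp, the 10 with the highest 4-OHT score and no EtOH summit within 1000 bp, the 5 highest kept, 5 each way between the EtOH lists, Taf7, Taf10, Taf12 and Tbp, up to 4 members per fixed list with those not kept first, and the 3 highest summits per class without a protein-coding gene. Further list members, such as kept ones, were named after their values were seen.

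Alternatives set beforehand were shared distances of 100, 500 and 1000 bp, gene end distances of 250, 1000 and 2000 bp, scores of at least 10, equal list lengths, the higher-scoring 50% of a list, 1 summit per peak, autosomes and X only, and no score matching; lists of equal length over all 4 groups and EtOH lists shortened to the 4-OHT length were added later, with tied scores at the end of a shortened list taken by position, in reverse, all or not at all. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with figures by matplotlib 3.10.9. The code was tested on 200 simulated second lists made from the 2666 RT7 EtOH summits. Random sets of 100 summits kept 20 percentage points more often than others of their score lay above the central 95% in 98.5% of simulations, and unchanged sets in 1% of them. Smaller sets were not simulated. Most fixed lists held fewer summits, such as 9 and 12 for pluripotency genes in RT7 and RT10 EtOH, so the 98.5% does not cover them. For such lists a percentile inside the central 95% does not show that keeping was unchanged. The permutation bound for sites missing in both lines was passed in 2.5% of simulations with independent losses and in 100% with shared ones. In these simulations both lines had the same EtOH list and the same scores. Error in the scores between lines was therefore not simulated, and the 2.5% does not cover it.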

Results

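TFIID, the general transcription factor that carries the TATA-binding protein TBP and its associated factors (TAFs) to RNA polymerase II promoters, was profiled on chromatin in 2 mouse embryonic stem (ES) cell lines. RT7 cells are homozygous for a floxed Taf7 allele and RT10 cells for a floxed Taf10 allele. Both carry a Cre recombinase fused to a ligand-responsive oestrogen receptor at the Rosa26 locus, and received 4-hydroxytamoxifen (4-OHT), which induces the deletion, or ethanol (EtOH) from day 1 to day 3 of culture. CUT&RUN releases DNA around an antibody-bound protein with a tethered nuclease. The series held 36 libraries in 20 groups, with 2 libraries per line and treatment for each of TBP, TAF7, TAF10 and TAF12 and 1 for the IgG control. The values analysed here were 4 lists of TBP peak summits, 1 per line and treatment, each called against the IgG library of the same line and treatment. TAF7, TAF10 and TAF12 binding was not analysed here, so the level of the deleted subunit in each group was not checked. The read depth behind each list is unknown, and with 1 list per group no difference between treatments had a replicate check. All percentages of summits carry exact 95% binomial intervals, which cover counting error only.

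The first comparison asked where TBP lay before and after deletion of Taf7. In RT7 cells TBP summits remained at most of the highest-scoring sites of the EtOH list. Among them were sites near ends of core histone genes, of Calr, which encodes the chaperone calreticulin, and of Med16, a Mediator subunit. Summits were absent from the 4-OHT list at Zfp42, Klf5, Trim28 and Tbx3 among pluripotency genes and at Rpl6, Rps6 and Rplp2 among ribosomal protein genes. The EtOH list held 2666 summits and the 4-OHT list 1379, or 51.7% as many. Of the EtOH summits, 1033 had a 4-OHT summit within 250 bp, a share of 38.7% (36.9 to 40.6), against 0.863% after the EtOH positions were moved by 10 kb. In the other direction 75% (72.6 to 77.2) of the 4-OHT summits had an EtOH summit within 250 bp.

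**Figure D1:**
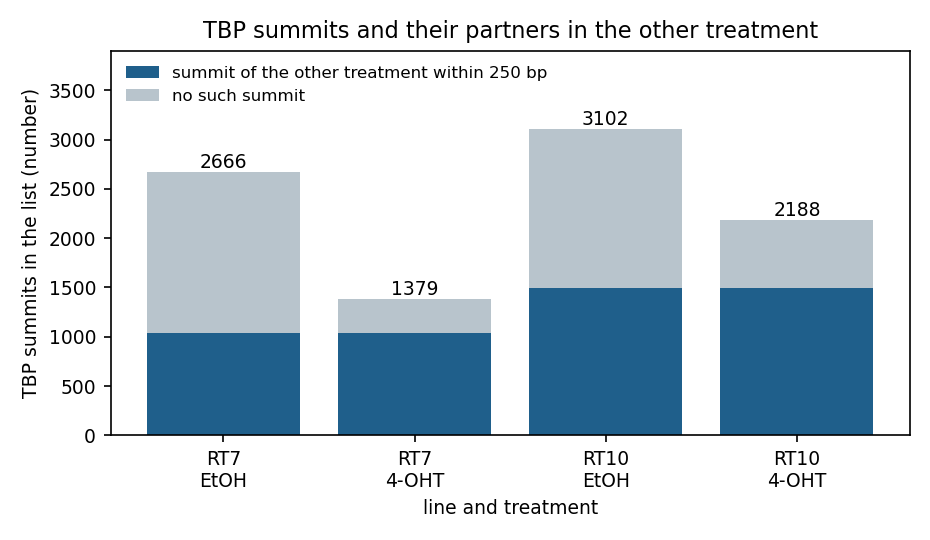
Number of TBP summits in each list (y axis) for each line and treatment (x axis); the dark part of a bar counts summits with a summit of the other treatment of the same line within 250 bp and the light part those without. The EtOH lists hold 2666 and 3102 summits and the 4-OHT lists 1379 and 2188, for RT7 and RT10.

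The 10 protein-coding genes with the highest EtOH scores and no 4-OHT summit within 1000 bp in RT7 had scores of 15.9 to 26.8, on the deposited −log10 q scale. Rpgrip1 led them (score 26.8), from a summit at position 52104229 of chromosome 14 (mm10), 12 bp from the end of Rpgrip1 (52104241 to 52161339) and within 500 bp of an end of Hnrnpc, which encodes an RNA-binding protein. Txn1, which encodes thioredoxin (chromosome 4, 57943373 to 57956411), had an EtOH score of 26.8 and lay 114391 bp from the nearest 4-OHT summit. The others were H1f3 (23.3), a linker histone gene, Rab5a (20.6), a GTPase of early endosomes, Anp32e (20.6), a chaperone of the histone variant H2A.Z, Pidd1 (19.4), Jup (18.2), which encodes plakoglobin, 6430548M08Rik (18.1), Gatad2a (17.3), a subunit of the NuRD complex, and Mdc1 (15.9), a mediator of the DNA damage checkpoint. The Pidd1 summit also lay at Rplp2. Of these 10 genes, 6 had a summit at the same place in the RT10 4-OHT list.

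Among the 10 protein-coding genes with the highest 4-OHT scores and no EtOH summit within 1000 bp in RT7, 4 lay 1053 to 1484 bp from an EtOH summit in tRNA or histone gene clusters. These were Aloxe3 (27.7), H1f1 (20.1), H1f3 (19.2) and H3c4 (16.5), the latter 3 on chromosome 13. H1f3 thus had its EtOH and 4-OHT summits 1053 bp apart. The other 6, with scores of 5.76 to 6.91, were Ddx39a, Plekhm1, Rmc1, Hmox1, which encodes haem oxygenase, Nfatc3 and Ilvbl, and all 6 had a summit in the RT10 EtOH list within 250 bp. At protein-coding gene ends the highest kept summits lay at H2bc4 with H2ac6 (score 167 in the EtOH list), Calr (138), Med16 with Gm24019 (135), H3c1 (129) and Cep95 with Ddx5 (120). Of the 2 mitochondrial summits, which scored higher, 1 was kept.

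Of 28 pluripotency genes, 9 had a TBP summit within 500 bp of either end in the RT7 EtOH list and 4 in the 4-OHT list. Pou5f1, Klf4 and Esrrb were among those without a summit in any of the 4 lists. A missing summit means that no peak was called there and does not by itself show that TBP was absent. Nanog (score 22.7), Tfcp2l1 (14.8), Klf2 (9.25) and Dppa3 (8.43) kept a summit, and Tbx3 (11.5), Trim28 (5.08), Zfp42 (5.08), Klf5 and Fgf4 had none. Among 79 ribosomal protein genes 29 were bound in EtOH and 19 in 4-OHT; Rplp2 (19.4), Rpl13a, Rpl6 and Rps6 (5.57 each) lacked a 4-OHT summit, and Rps26 (51.8), Rpl10 (34.7) and Rpl32 (34.3) had one. Glycolysis and cytoskeleton genes went from 10 to 5 bound members, with no 4-OHT summit at the tubulin genes Tuba1a (13.7) and Tubb5 (9.42) or at Cfl1 (10.4), cofilin. Immediate early and heat shock genes had 19 bound members in EtOH and 18 in 4-OHT, including Egr1 (53.3), Hspa8 (41.7) and Fosb (27.9), while Hspa1b (9.42) and Atf3 (7.45) had no 4-OHT summit. Replication-dependent histone genes had 36 and 33 bound members, and all 11 bound small nuclear RNA genes of RNA polymerase II, such as Rnu2-10 (35.8) and Rnu5g (29.4), were bound in both lists. The symbol pattern of the histone list also took H1f0 and H1f10, linker histone genes that are not tied to replication.

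Smaller lists gave few members in RT7. Small nucleolar RNA host genes had 10 bound members in EtOH and 7 in 4-OHT, with no 4-OHT summit at Snhg8 (17.1), Snhg3 (9.42) or Snhg18 (5.57). RNA polymerase II subunits and general factors had 5 and 3, with Polr2a (41) bound in both lists and Polr2l and Gtf2h5 in EtOH alone. SAGA and ATAC subunits had 4 and 1, with Tada3 (28.9) bound in both lists and no 4-OHT summit at Taf6l (10.4), Usp22 (7.45) or Eny2 (6.49). TFIID subunits had 3 and 1, with Taf13 bound in both lists and Taf8 and Taf4 in EtOH only. Cholesterol synthesis genes had 4 and 2. Eomes among lineage genes, Fn1 among fibroblast markers and Bax among p53 targets were the single bound members of their lists in EtOH, and of these Bax alone was bound in 4-OHT. No gene of the two-cell-like list had a summit in any of the 4 lists. When the EtOH list was shortened to its 1379 highest scores, 5 pluripotency genes were bound, against 4 in the 4-OHT list of that length. For ribosomal protein genes the count was 15 to 21, depending on which summits at the tied lowest score (5.57) are taken, so it lies on neither side of the 19 in 4-OHT. At that length the EtOH list bound 1 cholesterol synthesis gene, against 2 in 4-OHT, 0 to 1 TFIID subunits, against 1, and 17 to 18 immediate early and heat shock genes, against 18. It still bound more glycolysis and cytoskeleton genes (7 to 8, against 5) and more SAGA and ATAC subunits (4, against 1).

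The same comparison for Taf10 was made in RT10 cells. At protein-coding gene ends the kept summits with the highest scores again lay at Calr (144), H2ac6 with H2bc4 (135), Med16 with Gm24019 (122) and H3c1 (118), with Arrdc2 (103) after them. Of the 2 mitochondrial summits, which scored higher, 1 was kept. Mt1, a metallothionein gene, Slbp, which encodes the binding protein of the histone mRNA stem loop, Ddit3, a stress-response transcription factor gene, and Zfp143, which encodes a transcription factor of small nuclear RNA genes, had no 4-OHT summit within 1000 bp. The RT10 EtOH list held 3102 summits and the 4-OHT list 2188, or 70.5% as many. A 4-OHT summit lay within 250 bp of 1492 EtOH summits, or 48.1% (46.3 to 49.9), against 0.935% after the 10 kb shift, and 68.1% (66.1 to 70.1) of the 4-OHT summits had an EtOH summit.

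The 10 genes of the RT10 EtOH list without a 4-OHT summit within 1000 bp had scores of 16.3 to 61.7. Hes7 (61.7) had a 4-OHT summit 1005 bp away, in a tRNA gene cluster of chromosome 11 that reaches to Aloxe3. Mt1 (28.8; chromosome 8, 94178883 to 94180327), Slbp (24.8; chromosome 5, 33640055 to 33652574), Ddit3 (19.9), Zfp143 (19.9; chromosome 7, 110061689 to 110095396), Impa2 (17.5) and Cyth2 (17.5) followed. Nabp1, Ggps1 with Arid4b and Catsperd with Lonp1 had scores of 16.3. The RT7 4-OHT list held a summit at 5 of these 10, among them Mt1 (23.5 in that list) and Slbp (9.15). Of the 10 genes with a 4-OHT summit and no EtOH summit within 1000 bp in RT10, Aloxe3 (66.6), H1f1 (19.1), H4c9 (12.3) and H3c4 (12.3) lay 1164 to 1828 bp from an EtOH summit. The other 6 were Rab5a (17.1), Mapre1 (13.1), Klhl28 (12.3), Cdkn2aip (12.3), Avpi1 (11.8) and Rhebl1 (11.2), and 4 of them had a summit in the RT7 EtOH list.

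In RT10, 12 pluripotency genes were bound in EtOH and 5 in 4-OHT. Zfp42 (16.3), Trim28 (10.8), Dppa3 (8.72) and Klf5 (4.06) had no 4-OHT summit, nor had Sox2 (1.70), Dppa2 (2.95) and Tdgf1 (2.44). The EtOH scores of Sox2, Dppa2 and Tdgf1 lay below the lower quartile of that list (3.75), and these genes had no summit in RT7 EtOH. Nanog (41.3), Klf2 (19.9), Tbx3 (18.7), Tfcp2l1 (7.18) and Fgf4 (6.67) had a 4-OHT summit. Ribosomal protein genes had 33 bound members in EtOH and 19 in 4-OHT, without a 4-OHT summit at Rps21 (16.3) and Rpl27 (10.6) and with one at Rps26 (64.8) and Rpl10 (48.1). Glycolysis and cytoskeleton genes had 15 and 9, without one at Pgk1 (10.8), Pkm (10.8), Tubb5 (6.77) or Cfl1 (5.84). Immediate early and heat shock genes had 19 and 17, with Egr1 (61.7), Fosb (42.3) and Hspa8 (39.5) in both lists. Histone genes had 35 and 36, and the 11 bound small nuclear RNA genes, led by Rnu5g (27.4), Rnu3b1 (22.6) and Rnu2-10 (21.1), were again bound in both lists. With the EtOH list shortened to the 2188 highest scores, 8 to 9 pluripotency genes and 27 to 28 ribosomal protein genes were bound, by the choice among tied scores, against 5 and 19 in the 4-OHT list. Glycolysis and cytoskeleton genes then had 12 to 13 against 9, and RNA polymerase II subunits and general factors 5 against 3. Lists that went the other way included immediate early and heat shock genes (13 to 16 against 17), cholesterol synthesis genes (2 to 3 against 4) and small nucleolar RNA hosts (8 against 9).

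Of the smaller lists in RT10, small nucleolar RNA hosts had 9 bound members in each list, with 8 in both, such as Gas5 and Zfas1 (19.9 each), and Snhg3 (4.93) in EtOH only. RNA polymerase II subunits and general factors had 6 and 3, without a 4-OHT summit at Gtf2h4 (12.9), Gtf2f1 (5.21) and Polr2b (2.44). SAGA and ATAC subunits had 3 in each list, including Taf6l (19.9) and Tada3 (12.1) in both, and TFIID subunits 2 and 1. Among p53 targets 4 and 2 were bound, with no 4-OHT summit at Pmaip1 (4.93) or Rrm2b (4.06), and among cholesterol synthesis genes 4 in each list, with Idi1 (8.72), Mvk (4.06) and Acat2 (3.23) in EtOH only. Eomes (1.41) and Fn1 (3.75) were bound in EtOH alone, as in RT7. A summit within 500 bp of a gene's end was not assigned to that gene alone, since neighbouring genes such as Hspd1 and Hspe1 shared summits.

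**Figure D2:**
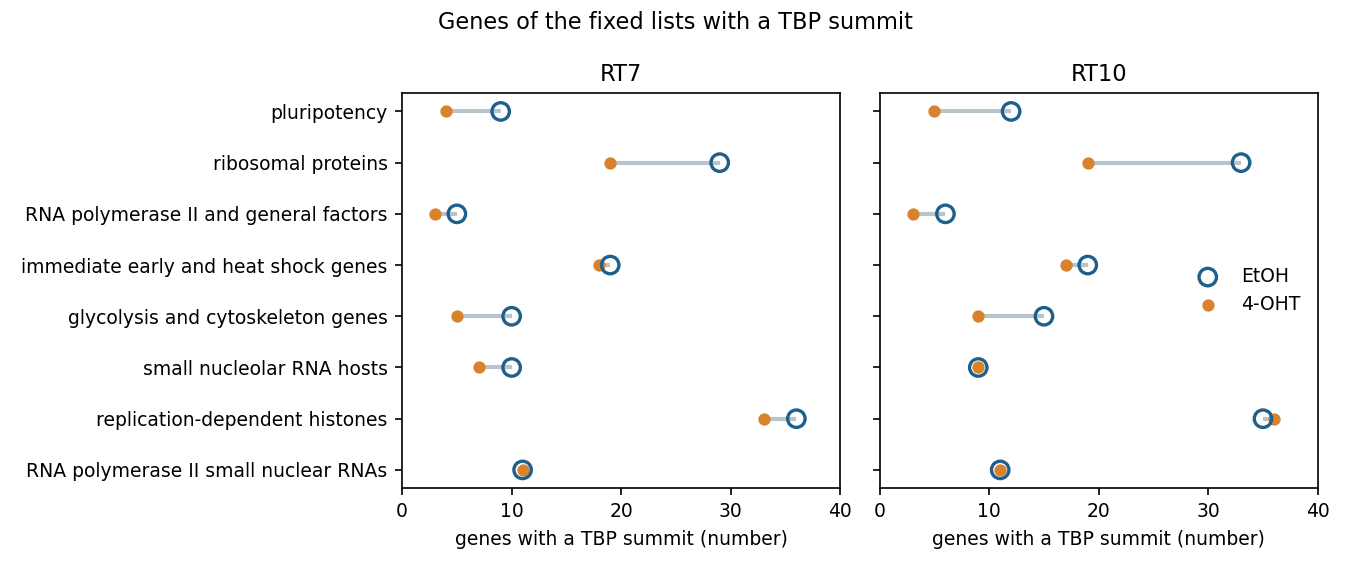
Number of genes with a TBP summit within 500 bp of either end (x axis), by fixed list (y axis), in RT7 and RT10. Shown are the fixed lists with at least 5 EtOH summits in both lines, without the RNA polymerase III genes. Open circles are EtOH lists and filled circles 4-OHT lists. Pluripotency genes went from 9 to 4 and from 12 to 5, small nuclear RNA genes stayed at 11 in both lines.

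To set these lists against each other within a score range, the share kept (with a 4-OHT summit within 250 bp) was placed among 10000 random sets of EtOH summits of the same scores. The 11 small nuclear RNA genes of RT10 kept every summit, at percentile 99.6, and were the only case above the central 95% among the 18 list and line combinations with at least 5 summits, with 0 below it, at this distance. In RT7 the same genes kept 9 of 11 summits (percentile 95.5), and 11 of 11 with partners up to 500 bp away (percentile 99.9). At 500 bp the list of RNA polymerase III genes also lay above the central 95%, in RT7 and in RT10 (100 in both after rounding). Ribosomal protein genes kept 62.1% (42.3 to 79.3) of their EtOH summits in RT7 and 48.5% (30.8 to 66.5) in RT10, at percentiles 94.4 and 21.3, and pluripotency genes 44.4% (13.7 to 78.8) and 41.7% (15.2 to 72.3), at percentiles 56.1 and 16.2. Immediate early and heat shock genes lay at percentiles 88.4 and 90.0, glycolysis and cytoskeleton genes at 15.1 and 42.2. Histone genes kept 22 of 28 and 25 of 27 summits, at percentiles 36.3 and 80.0.

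TBP also serves RNA polymerases I and III, so summits were divided by the gene end nearest to them. Summits at RNA polymerase III genes, nearly all of them tRNA genes, were about as many in both treatments, with 157 in EtOH and 148 in 4-OHT for RT7 and 158 and 168 for RT10. Those at protein-coding gene ends numbered 928 and 466 in RT7 and 1038 and 665 in RT10. In EtOH lists shortened to the 4-OHT length, 502 and 749 summits lay at protein-coding gene ends and 136 and 145 at RNA polymerase III genes, for RT7 and RT10, of which the latter lie below the 148 and 168 of the 4-OHT lists. Among the highest-scoring RNA polymerase III summits were those at n-TEctc11 (88.0, chromosome 13, position 21160985), n-TWcca7 (78.2, chromosome 11, position 69041684) and n-TPtgg4 (58.8) in RT7 EtOH, each with a summit within 250 bp in all 4 lists. Rmrp, the RNA of a mitochondrial RNA-processing ribonuclease, and the Y RNA gene Rny1 were bound in all 4 lists. Rpph1, the RNase P RNA gene, was bound in 3, without RT7 4-OHT.

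At 250 bp, 69.4% (61.6 to 76.5) of RNA polymerase III summits in RT7 and 77.2% (69.9 to 83.5) in RT10 were kept, at percentiles 95.1 and 93.9 among score-matched sets. Counting partners up to 1000 bp away, as within tRNA clusters, these shares were 89.8% and 93.7%, at percentile 100 in both lines, and the shares of protein-coding gene ends 45.4% and 53.5%, at percentiles 1.02 and 0. In clusters a neighbouring gene's summit can count as the partner at that distance. Among RNA polymerase III summits with no other EtOH summit within 5 kb, 24 of 35 in RT7 were kept at 250 bp (68.6%, percentile 71.6) and 77.1% at 1000 bp (percentile 89.9), and 33 of 38 in RT10 (86.8%, percentile 99.6) and 94.7% (percentile 100). Protein-coding gene ends kept 40.9% (37.8 to 44.2) and 48.5% (45.4 to 51.5) at 250 bp. All summits of the same scores, protein-coding gene ends included, kept 40.7% and 50% (percentiles 58.2 and 7.82). Other gene ends kept 52.0% and 54.1% (percentiles 99.7 and 92.0), and summits away from any gene end 31.8% (29.3 to 34.3) and 44.2% (41.8 to 46.6), at percentiles 0.98 and 52.4. Among summits with no other EtOH summit within 5 kb, protein-coding gene ends lay at percentiles 20.1 in RT7 and 1.61 in RT10 at 1000 bp. At 250 bp the other gene ends of RT7 then lay at percentile 94.1 and its summits away from gene ends at 7.7, both inside the central 95%.

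Between 45.9% and 53.7% of summits lay within 500 bp of a gene end. The shares were 48.3% (46.4 to 50.3) in RT7 EtOH, 53.7% (51.1 to 56.4) in RT7 4-OHT, 46.4% (44.7 to 48.2) in RT10 EtOH and 45.9% (43.8 to 48.0) in RT10 4-OHT, against 8.45% to 9.35% after a shift of 10 kb. Of the summits away from gene ends in RT7 EtOH, 52.4% lay inside a gene. The highest intergenic summit in RT7 EtOH lay at position 128838290 of chromosome 6 (61.3), 3980 bp from LOC115490435, and was present in all 4 lists, as was 1 at position 128764361, 14124 bp from Klrb1c (54.8). No list had a summit near Taf7, Taf10 or Tbp, the nearest being 291565 bp from Tbp. The nearest summit to Taf12 lay 3770 to 4154 bp away, at the small nuclear RNA gene Rnu11.

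Keeping followed the EtOH score. In RT7 the share with a 4-OHT summit was 14.4% (11.6 to 17.7) among the 20% of summits with the lowest scores and 83.3% (79.9 to 86.4) among the 20% with the highest, and in RT10 19.5% (16.4 to 22.8) and 87.4% (84.6 to 89.9). Kept summits had median EtOH scores of 11.5 in RT7 and 10.2 in RT10, and the others 4.68 and 4.06.

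**Figure D3:**
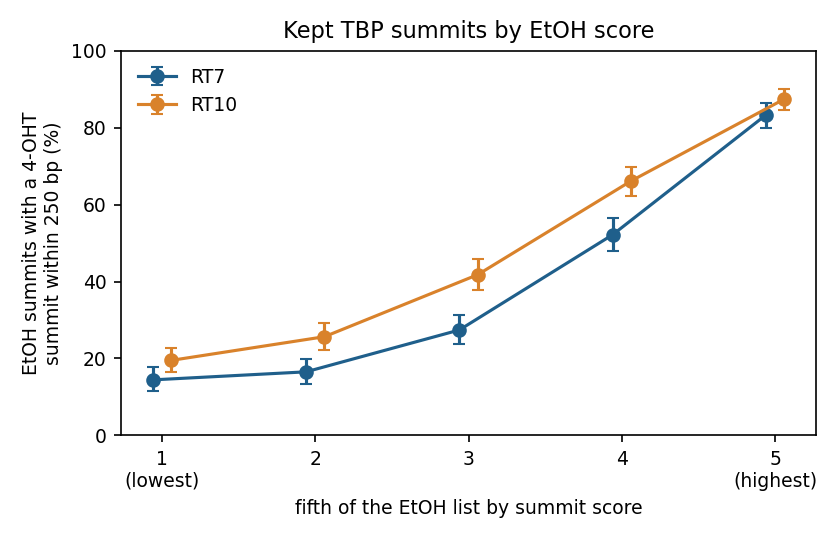
Percent of EtOH summits with a 4-OHT summit within 250 bp (y axis) in 5 groups of equal size by EtOH score (x axis), for RT7 and RT10; bars are exact 95% binomial intervals. The share runs from 14.4% to 83.3% in RT7 and from 19.5% to 87.4% in RT10.

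The lists of the EtOH-treated lines were compared to see how far lists differ without a deletion. Both held strong summits at Calr, Med16, Polr2a, Tubb4b and Egr1. Of the RT7 EtOH summits, 65.0% (63.2 to 66.8) had an RT10 EtOH summit within 250 bp, and 55.7% (53.9 to 57.4) of the RT10 summits had one in RT7. The genes with the highest scores in RT7 alone were H4c9 (34.7), H1f3 (23.3), Rab5a (20.6), 6430548M08Rik (18.1) and Rhebl1 (14.6), and in RT10 alone H1f3 (40.9), H3c2 (27.4), Zfp444 (13.9), Ubald1 (13) and Gtf2h4 (12.9). The 2 summits of H1f3 lay 1080 bp apart.

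The 4-OHT lists set the Taf7 and Taf10 deletions side by side. In RT7 4-OHT 68.2% (65.6 to 70.6) of summits had a partner in RT10 4-OHT, and 43.0% (40.9 to 45.1) in the reverse direction. Genes of the fixed lists bound in both were, for example, Nanog, Rps26, Egr1, Fosb, Polr2a and Taf13. Since list lengths differed, all 4 lists were also shortened to their 1379 highest scores, a choice made after seeing the lengths. The shares were then 59.0% (56.3 to 61.6) for RT7 EtOH with RT7 4-OHT, 61.3% (58.7 to 63.9) for RT10, 62.4% (59.7 to 64.9) between the EtOH lists and 57.9% (55.2 to 60.5) between the 4-OHT lists.

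**Figure D4:**
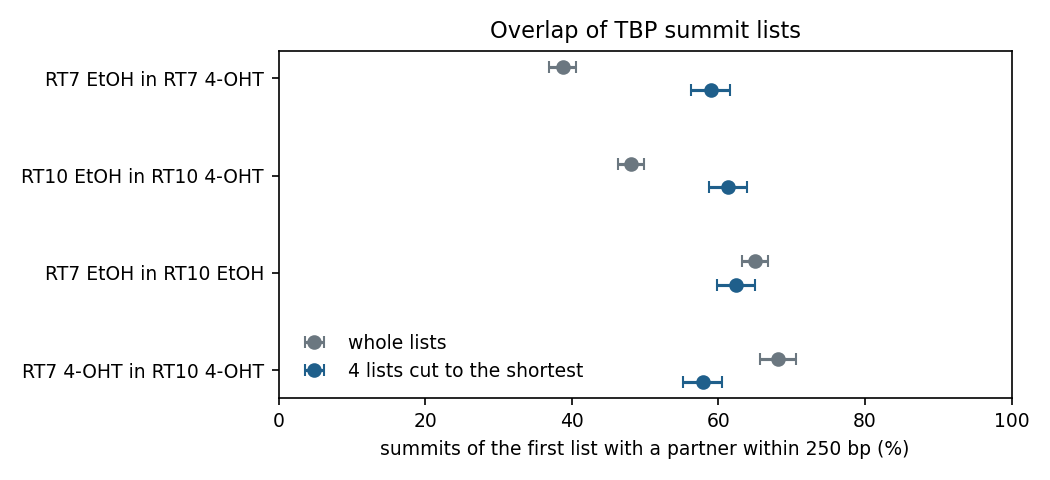
Percent of summits of the first list with a summit of the second within 250 bp (x axis) for 4 pairs of lists (y axis), for whole lists and for all 4 lists shortened to 1379 summits; bars are exact 95% binomial intervals. At equal length the shares lie between 57.9% and 62.4%.

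Sites present in both EtOH lists were followed into both 4-OHT lists. Of 1733 such sites, 745 had a 4-OHT summit in both lines, 428 lacked it in RT7 alone, 145 in RT10 alone and 415 in both. The product of the separate counts gives 272, and permuting the RT10 labels among sites of similar score gave a mean of 370 (central 95% 355 to 385), with 0 of 10000 permutations reaching 415. The protein-coding genes with the highest mean of both EtOH scores and no summit in either 4-OHT list were Rpgrip1 with Hnrnpc, Zfp143, Mdc1, Asf1b, a histone chaperone gene, Rtn4, Arid4b with Ggps1, Ddit3 with Mbd6, Ephb3, Nufip2, Eif5, Chchd2 and Nabp1. Among fixed-list genes bound in both EtOH lists, Klf5, Zfp42 and Trim28 of 9 pluripotency genes and Rpl6, Rps6 and Rps21 of 24 ribosomal protein genes had no summit in either 4-OHT list. The same held for Hspa1b of 16 immediate early and heat shock genes and for 0 of 11 small nuclear RNA genes.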

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

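The tests of list length, of protein-coding gene ends and of summit movement below were chosen after the results were seen; those on sites missing from both 4-OHT lists were set before their results.

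In whole lists several counts went in opposite directions in RT7 and RT10, and none of these differences between lines was tested. Summits at RNA polymerase III genes numbered 157 in EtOH and 148 in 4-OHT for RT7, and 158 and 168 for RT10. Bound RNA polymerase III genes numbered 190 and 185 in RT7, and 188 and 191 in RT10. Bound histone genes numbered 36 and 33 in RT7, and 35 and 36 in RT10. Summits at any gene end made up 48.3% and 53.7% in RT7, and 46.4% and 45.9% in RT10. For RNA polymerase III and histone genes the opposition did not hold at equal list length. With the EtOH lists shortened to the 4-OHT length, RNA polymerase III summits were 136 and 148 in RT7 and 145 and 168 in RT10, bound RNA polymerase III genes 178 and 185, and 180 and 191, and bound histone genes 33 and 33, and 35 and 36. Gene end shares were then 49.4% and 45.9% in RT10, and 55.1% and 53.7% in RT7, where the choice among tied scores (53.4% to 57.4% in EtOH) leaves the direction undecided. At scores of at least 10 they were higher in 4-OHT in both lines, 61.8% and 66.3% in RT7, and 57.9% and 61.4% in RT10. Mitochondrial DNA, which entered list totals and overlaps but no gene class, held 2 summits in each list, with the 2 highest scores of the list. The higher of these scores was 521.8 in RT7 EtOH, 364.0 in RT7 4-OHT, 934.1 in RT10 EtOH and 653.8 in RT10 4-OHT.

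RNA polymerase III genes had similar summit counts in both treatments while a part of their EtOH summits lacked a 4-OHT partner within 250 bp. Whether these summits moved within a tRNA cluster or a wide peak cannot be told apart from their loss beside a kept neighbour. Of the 48 such summits in RT7, 66.7% had a 4-OHT summit within 1000 bp, and of the 36 in RT10 72.2%, against 7.48% and 9.72% at protein-coding gene ends, but in clusters the partner can belong to the next tRNA gene. Among those with no other EtOH summit within 5 kb, 3 of 11 in RT7 (27.3%, 6.02 to 61.0) and 3 of 5 in RT10 (60%, 14.7 to 94.7) had one, too few to decide. Reads shared between tRNA gene copies could not be examined in summit lists and stay open.

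The 4-OHT lists were shorter, and EtOH sites without a 4-OHT summit might reflect only a list shortened along a similar ranking of sites, from fewer reads, a weaker signal everywhere or the q threshold. With all 4 lists at 1379 summits, RT7 EtOH shared 59.0% (56.3 to 61.6) with RT7 4-OHT and RT10 EtOH 61.3% (58.7 to 63.9) with RT10 4-OHT, with intervals that overlap that of the EtOH lists of both lines (62.4%, 59.7 to 64.9). No pair of lists of the same line and treatment shows the overlap of unchanged cells, and the shortened lists end at scores of 5.57, 1.30, 6.77 and 4.53 (RT7 EtOH and 4-OHT, RT10 EtOH and 4-OHT), so list length and site-specific loss cannot be told apart in either line. The tables argue against a loss at protein-coding gene ends of at least 5 percentage points beyond sites of the same score away from gene ends in RT7, where the difference was 1.99 (−1.45 to 5.38) at 250 bp, 0.901 (−2.62 to 4.37) at 500 bp and −0.565 (−3.99 to 2.85) at 1000 bp. In RT10 a loss of that size stays open, with −2.18 (−5.47 to 1.14), −2.90 (−6.06 to 0.243) and −4.73 (−7.99 to −1.58). Gene ends were taken without strand, and 52.4% of the RT7 EtOH summits away from them lay inside a gene. Loss at promoters as such was therefore not tested in either line. Against all summits of the same score, RNA polymerase III and other gene ends included, the differences at 1000 bp were −2.59 (−5.83 to 0.673) in RT7 and −4.12 (−7.21 to −1.05) in RT10; a difference between the deletions was not tested.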

How the results depend on the processing

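Summit counts, overlaps, gene end shares, kept shares and percentiles of classes and fixed lists, bound members, median scores and sites missing in both lines were recomputed under settings chosen beforehand. The kept shares by score, the site patterns over 4 lists, the chromosomes and the summits with no other EtOH summit within 5 kb were not. The reverse shares under these alternatives, equal lengths over all 4 lists, shortened EtOH lists (the only alternative for summits per class) and the handling of tied scores were chosen after the data were seen. No paired analysis was possible because each group has 1 list with no values per replicate, and for the same reason no replicate could be left out. The TATA box split and its alternatives were not run, as no genome sequence was used. Counting 1 summit per peak and leaving out mitochondrial summits moved no count or overlap beyond its error; the first of these altered nothing, since no peak had several summits. For the changes below the cause was not tested beyond what each setting itself does. At a score of at least 10 the lists held 764 and 350 summits in RT7 and 913 and 630 in RT10. In the order RT7 EtOH in 4-OHT, RT10 EtOH in 4-OHT, RT7 in RT10 EtOH and RT7 in RT10 4-OHT, the overlaps were 27.1%, 33.6%, 47.0% and 47.8% at 100 bp, 43.3%, 52.8%, 71.6% and 76.0% at 500 bp, and 46.0%, 55.6%, 74.5% and 79.2% at 1000 bp. For the 50% of the first list with the highest scores they were 60.2%, 71.1%, 80.6% and 83.2%, with both lists cut to the shorter 59.0%, 59.6%, 61.5% and 57.9%, and with all lists cut to the shortest 59.0%, 61.3%, 62.4% and 57.9%, or 58.9%, 61.2%, 61.8% and 57.8% with tied scores taken in reverse order. With scores of at least 10 in both lists they were 51.0% in RT10, 69.5% between the EtOH and 77.1% between the 4-OHT lists, and RT7 stayed within its interval. Several directions depend on the setting. As a share of EtOH summits, whole lists gave less overlap within RT7 and RT10 than between the EtOH lists, and equal lengths narrowed that gap; as a share of 4-OHT summits, overlap within RT7 (75%) and RT10 (68.1%) was above that between the EtOH lists (65.0%). As a share of RT7 summits, the EtOH lists shared less than the 4-OHT lists at whole length (65.0% and 68.2%) and more at equal length; as a share of RT10 summits they shared more at whole length (55.7% and 43.0%). The RT10 gene end share was lower in 4-OHT at every distance and higher at scores of at least 10. With EtOH lists shortened to the 4-OHT length, gene end shares of 55.1% in RT7 and 49.4% in RT10 stood against 53.7% and 45.9% in 4-OHT; for RT7 the choice among tied scores (53.4% to 57.4%) leaves the direction undecided. With EtOH lists shortened to the 4-OHT length, RNA polymerase III summits (136 and 148 in RT7), RNA polymerase III genes (178 and 185), immediate early and heat shock genes (17 and 18 in RT7, 16 and 17 in RT10), small nuclear RNA genes (8 and 11 in RT7) and cholesterol synthesis genes (1 and 2 in RT7, 2 and 4 in RT10) were more in 4-OHT, as were RT10 snoRNA hosts (8 and 9) and RT10 summits away from gene ends (1105 and 1182); of these only the RT7 immediate early count (17 to 18) reaches its 4-OHT value under another choice among tied scores. For RT7 ribosomal protein genes (15 to 21 against 19), other gene ends (113 to 130 against 127) and no gene end (585 to 641 against 636) the choice among tied scores can turn the direction, and for RT7 TFIID genes (0 to 1 against 1) it can make the counts equal. In the order RT7 EtOH, RT7 4-OHT, RT10 EtOH and RT10 4-OHT, gene end shares were 39.1%, 42.7%, 37.8% and 35.8% at 250 bp, 54.7%, 60.7%, 52.3% and 52.1% at 1000 bp, 62.0%, 67.7%, 59.9% and 59.3% at 2000 bp, 37.8%, 37.8%, 36.4% and 33.5% for protein-coding genes alone, and 61.8%, 66.3%, 57.9% and 61.4% at scores of at least 10. Among classes, a shared distance of 500 bp gave 80.9% and 36.1% in RT7 for RNA polymerase III genes and no gene end, and 52.3%, 88.6% and 48.6% in RT10 for protein-coding gene ends, RNA polymerase III genes and no gene end. At 1000 bp, protein-coding, RNA polymerase III, other and no gene ends kept 45.4%, 89.8%, 62.3% and 39.0% in RT7 and 53.5%, 93.7%, 66.4% and 51.8% in RT10. Of the fixed lists, RNA polymerase III genes kept 85.0% and 90.6% in RT7 and 90.7% and 93.8% in RT10 at 500 and 1000 bp, and small nuclear RNA genes and the single p53 target summit of RT7 100% at both. The other 112 list values stayed within their intervals, which are wide. Of 210 alternative counts of bound members, those from shortened EtOH lists included, 26 moved beyond 1.5-fold. Of 6 counts of named list members with a 4-OHT summit, taken at other shared distances, 3 did. At 1000 bp the median score of kept RT10 summits was 9.70. Among sites with scores of at least 10 in both EtOH lists, 17 lacked a 4-OHT summit in both lines. Without score matching, or at other distances, 29 of 130 percentiles left the central 95%, among them protein-coding gene ends at 1000 bp (1.06 in RT7 and 0 in RT10), RNA polymerase III summits at 500 and 1000 bp (100 in both lines) and small nuclear RNA genes of RT7 at 500 and 1000 bp (99.9).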

Other observations

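Beyond treatment, sites could be sorted by their presence over all 4 lists, a division chosen after seeing the lists. In all 4 lists, 744 RT7 EtOH summits had a partner, with a median score of 14.4, and 289 of them lay at protein-coding gene ends and 83 at RNA polymerase III genes. Both EtOH lists and neither 4-OHT list, with no 4-OHT summit within 1000 bp, held 347 sites, of which 177 lay away from any gene end, 149 at protein-coding gene ends and 1 at an RNA polymerase III gene. They include Chchd2 (13.7 in RT7 EtOH, 9.22 in RT10 EtOH), Smim7 (12.6, 5.44) and the metallothionein gene Mt2 (12.6, 2.00). The RT10 EtOH score of Mt2 lay near the lowest of that list (1.36). Beside Mt2 lies the neighbouring gene Mt1, whose summit was missing from RT10 4-OHT alone. The reverse pattern, both 4-OHT lists and neither EtOH list, covered 19 sites. The 5 highest of these lay in tRNA and histone gene clusters, at Aloxe3 (27.7), H1f1 (20.1), H3c4 (16.5), n-TRtcg3 (13.7) and n-TDgtc13 (10.8).

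Some sites were listed in both treatments of a single line. RT10 lists held 191 sites that neither RT7 list had, and RT7 lists 42 that neither RT10 list had. The RT10 lists were longer, and these counts were neither repeated at equal length nor tested against variation between lists. Away from any gene end lay 73.8% of the RT10 sites and 71.4% of the RT7 sites, against 39.5% of the sites in all 4 lists. These shares were not matched on score. The median EtOH score was 5.70 for the RT10 sites and 5.57 for the RT7 sites, and 14.4 in RT7 EtOH for sites in all 4 lists. Of the sites in both EtOH lists and neither 4-OHT list, with a median score of 4.68, 51.0% lay away from gene ends. The strongest RT10 site lay at position 84653232 of chromosome 8 in both treatments, 8099 bp from Ier2, with scores of 90.3 in EtOH and 67.6 in 4-OHT. The strongest RT7 site lay at position 121832820 of chromosome 8 (36.1), 1171 bp from Gm42048. The X chromosome had 25 EtOH and 7 4-OHT summits in RT7, and 36 and 15 in RT10, with 24.0% (9.36 to 45.1) and 30.6% (16.3 to 48.1) kept, at percentiles 31.4 and 1.24 among score-matched sets, in a scan of all chromosomes.

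Sites missing from both 4-OHT lists were more numerous than score-matched permutations gave, 415 against a mean of 370, and this was weighed as a hypothesis that the lines share a set of sensitive sites. Summits displaced by 250 to 1000 bp do not account for the excess. With 1000 bp used both to pair the EtOH sites and to call a missing summit, 392 sites lacked one in both lines, against a central range of 303 to 335. That run covered 1987 sites, against 1733 at 250 bp, so the 392 and the 415 come from different sets of sites. An excess also remained when sites with low EtOH scores were left out, a filter that cannot remove weak sites whose scores came out high. Among sites with scores of at least 10 in both EtOH lists 17 were missing in both against a range of 6 to 15, though this rests on few sites. What stays open is that scores measure site strength with error, so that sites of equal score could still differ in strength in the same way in both lines, and that 4-OHT or Cre activity acted on both lines apart from the deletions, since no line without a floxed allele was analysed here. A shared need for TFIID at these sites may be a further explanation and was not tested.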
